A study of Homo sapiens with 7 samples.

How the data were processed

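RNA bound by the J2 antibody, which recognises double-stranded RNA, was sequenced from 7 libraries of HCT116, a human colon carcinoma line. Per the labels, lysates were treated with RNase T1 and DNase, the recovered double-stranded RNA was sheared, and libraries were made with a kit for small RNA. Per the labels, cells received 0.3 µM of 5-Aza-CdR (5-aza-2'-deoxycytidine, an inhibitor of DNA methylation), the medium was replaced after 24 h, and cells were kept to day 5. The labels name 4 treatments: PBS, 5-Aza-CdR, Vc and Combination. They spell out no dose for Vc and do not define the Combination; in the study's published account Vc is vitamin C and the Combination is 5-Aza-CdR with vitamin C.

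The authors deposited repeat counts as 2 workbooks, called here set 1 and set 2. Set 1 holds 1 library each of PBS, 5-Aza-CdR and the Combination. Set 2 holds 1 library each of PBS, Vc, 5-Aza-CdR and the Combination, and its name states that duplicates were marked; whether marked reads were removed before counting, and whether both sets were aligned and counted alike, was not given in the sources used here. Deposited values in the family sheets and the locus sheets are raw read counts, and both were used as a count of reads per family of long terminal repeat (LTR) elements or per annotated copy. A further sheet of set 1 gives, per the file headers, a ratio, the count of each family divided by the number of tRNA reads of its library; the tRNA number of each library was recovered from these ratios. Whether the tRNA reads were counted in the same J2 libraries was not given in the sources used here, so tRNA-scaled values are relative to that number whatever its origin. The labels name the genome build hg19 for all samples, and the submitters' processing notes name Bowtie2 and Picard for set 2. The aligner of set 1, the counting tool and the treatment of reads that map to several copies were not given in the sources used here. Coordinates are hg19 and 1-based, with each start 1 above the start given in the locus sheets. Genes near the loci were not analysed here.

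The family sheets held between 11531 reads (5-Aza-CdR, set 1) and 32403 reads (Combination, set 2) per library. Shares of reads carry Wilson 95% intervals, and ratios between 2 libraries carry exact conditional binomial 95% intervals. A family with 0 reads in a library was placed at a floor of 3 counts per library. Ratios of the HERV-Fc families used the normalised library sizes of the joint fit below, unless said otherwise. These intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

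A rule was written to find whether the sets hold the same libraries: at 95% or more of the loci with reads in set 2, set 1 would hold at least as many reads. The observed percentages were 6.87 for PBS, 7.00 for 5-Aza-CdR and 7.68 for the Combination, so the sets were treated as different libraries. The rule shows only that the reads of set 2 are not a part of those of set 1. A second sequencing of the same library, with few reads per locus, could also miss the 95%, so the rule does not exclude it. The labels mark the PBS, 5-Aza-CdR and Combination samples of set 2 as v2 without defining it. They do not say whether the libraries of the sets came from separate cultures. Within a set, where each treatment has 1 library, values are descriptive and carry no test. Set 1 was scaled by the tRNA number of each library. Set 2, which gives no tRNA number, was scaled by the total reads counted in families, so its total is fixed at no change by construction. Log2 ratios had 0.5 added to each count, and counts of families with ratios of at least 2-fold used families with at least 100 reads over the libraries of the set.

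All 7 libraries were then fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, trimmed mean of M-values normalisation, edgeR's default filter on low counts), with treatment and set as terms. The plan named the tRNA numbers as the scaling of this fit where they were the main scaling. Set 2 gives none, and the fit used the trimmed mean, which takes the typical family as unchanged. The fit tested 352 families, with 2 residual degrees of freedom, 8.92 prior degrees of freedom and a biological coefficient of variation of 0.304. P-values were adjusted by the Benjamini-Hochberg method over the families tested, at a threshold of 0.05. Intervals of fitted log2 changes are 95% intervals from the same test. The contrasts of 5-Aza-CdR with PBS, of the Combination with PBS and of the Combination with 5-Aza-CdR were chosen before the data were examined, as were the lists, the rule for named families, and all alternatives not stated below to be later. The contrast of the single Vc library, the contrast of the Combination with the sum of the single agents, and a fit of 409 loci with at least 30 reads, with its own alternatives, were added after seeing the data. No treatment had more than 2 libraries, so no regrouping of samples was tested.

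Lists were made by family name: LTR12 and HERV9; LTR7 and HERVH; LTR5 and HERVK; LTR17 and HERV17; LTR2 and HERVE; LTR10 and HERVI; HERV-Fc; THE1; MST; MLT1; MLT2 and HERVL; families named MER; internal regions; and LTRs. The HERV-Fc list also held HERVFH19-int and HERVFH21-int. Lists by repeat class, and a list of repeats other than LTR elements, could not be used because the sheets give no class. The median log2 ratio of each list with at least 3 members past the read minimum in a set, other than the list of LTRs, was ranked among 10000 random lists of the same size matched on mean count, with limits at percentiles 2.5 and 97.5. Named families were the 10 highest and 10 lowest by mean log2 ratio among those with the same direction in both sets, the 5 families with the most reads, all list members used as examples, and families past the threshold of the joint fit. Named loci were the 5 highest and 5 lowest with at least 30 reads in the compared libraries of each set and, where both sets held the comparison, the same direction. Few loci were eligible. For 5-Aza-CdR against PBS there were 16, with 10 of the same direction. For the Combination there were 21 and 13 against PBS, and 17 and 10 against 5-Aza-CdR. In these rules a family or locus that moved upward in both sets by a small amount can be among the lowest.

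The alternatives tried were other scalings, other filters, another pseudocount, another fold size, counts summed from the loci, leaving out the 5 most abundant families, DESeq2 1.42.0, fits without the term for the set, and leaving out each library in turn. For the list percentiles, a further alternative took single loci as list members and ranked their median among random sets of loci. Robust dispersion in edgeR was added after seeing the data. On simulated data with 60 of 352 families changed, in 5 simulations, the fit recovered 98.7% of families raised 8-fold and 67.6% of those raised 4-fold in the Combination against PBS, and 71.6% and 54.5% of those lowered 8-fold and 4-fold. It made 7 false calls in 1316 unchanged families. Apart from these changes the simulated libraries shared a common profile, with no difference between the sets and as many families lowered as raised. The rates may thus not hold for the data. On simulated counts the intervals held the true ratio in 96.2% of 2000 draws, and unchanged lists fell outside the limits in 5% of 300 draws. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.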

Results

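Double-stranded RNA was recovered from HCT116 cells, a human colon carcinoma line, with the J2 antibody, and reads were counted over families of endogenous retroviruses and their long terminal repeats (LTRs). There were 2 libraries each of PBS (the untreated control), 5-Aza-CdR and the Combination, and 1 library of Vc. Family counts summed to 23131 reads in PBS, 11531 in 5-Aza-CdR and 14319 in the Combination of set 1. In set 2 they summed to 19450 in PBS, 18495 in Vc, 23528 in 5-Aza-CdR and 32403 in the Combination. Set 1 also gives tRNA reads: 232558 for PBS, 38200 for 5-Aza-CdR and 15946 for the Combination. The series asks which double-stranded RNA appears after 5-Aza-CdR and after the combination treatment, compared with untreated cells. Treatments were compared within each set, where each has 1 library and intervals cover counting error. They were also compared in a joint edgeR fit of all 7 libraries, where PBS, 5-Aza-CdR and the Combination each have n = 2. Whether the 2 libraries of a treatment came from separate cultures, or were 1 library sequenced again, is not known.

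LTRs of the HERV-9 group (the LTR12 families, with the internal region HERV9-int) took a larger share of repeat reads in the 5-Aza-CdR and Combination libraries of both sets. In set 1 their share of family reads was 2.60% in PBS (95% Wilson interval 2.41 to 2.82), 18.5% in 5-Aza-CdR (17.8 to 19.2) and 24.1% in the Combination (23.4 to 24.8). In set 2 it was 5.69% in PBS (5.37 to 6.03), 5.54% in Vc (5.22 to 5.88), 25.2% in 5-Aza-CdR (24.7 to 25.8) and 31.2% in the Combination (30.7 to 31.7). LTR12C alone held 15.7% and 20.4% of family reads in the 5-Aza-CdR and Combination libraries of set 1, against 1.24% in PBS. In set 2 LTR12C held 21.8% and 26.7%, against 4.38% in PBS and 4.25% in Vc. These are shares of the family sheets, and the locus sheets of set 1 hold more reads (133279 in PBS), most of them at 1 HERVE_a-int locus. Of locus reads in set 1 the group held 0.452% in PBS, 5.46% in 5-Aza-CdR and 6.79% in the Combination.

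**Figure D1:**
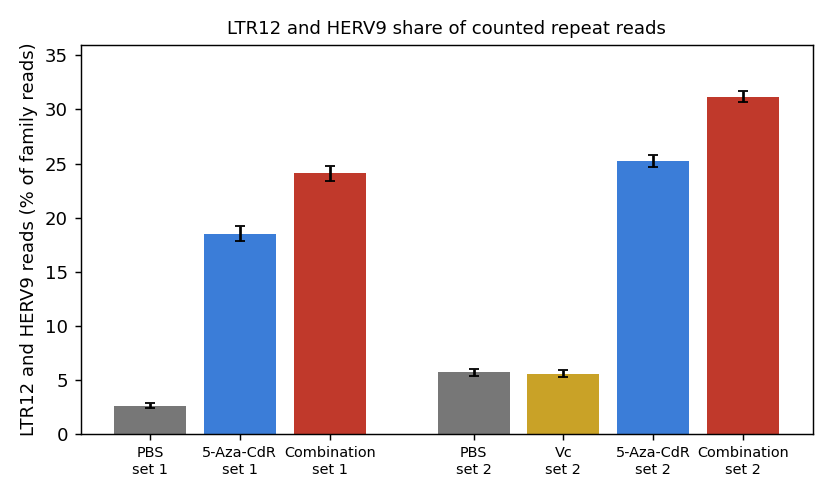
Share of family reads (%, vertical axis) assigned to the LTR12 families and HERV9-int in each of the 7 libraries (horizontal axis, treatment and set); bars are single libraries and error bars are 95% Wilson intervals. The 5-Aza-CdR and Combination libraries lie between 18.5% and 31.2%, the PBS and Vc libraries between 2.60% and 5.69%.

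The first comparison asks which repeats gained or lost double-stranded RNA after 5-Aza-CdR relative to PBS. In the joint fit, 5 of 352 families rose and 0 fell. Its normalisation takes the typical family as unchanged, so rises and falls in every joint fit are relative to the other repeats. A general gain, like that by tRNA in set 1, would not appear in it. LTR12C rose by 3.16 on the log2 scale (SE 0.51, adjusted p = 0.0085), LTR12 by 2.22 (SE 0.34, adjusted p = 0.0085), LTR12E by 2.43 (SE 0.43, adjusted p = 0.0125) and LTR48B by 2.81 (SE 0.53, adjusted p = 0.0197). HERV-Fc2-int, the internal region of the HERV-Fc2 provirus group, also rose (adjusted p = 0.00597). It had 0 reads in both PBS libraries, 10 reads in set 1 and 27 in set 2 after 5-Aza-CdR, which with the library sizes of the joint fit is at least 6.67-fold and at least 9.89-fold higher than a floor of 3 counts per PBS library, taking the treated reads as exact. Per counted repeat read and with counting error in both libraries, the lower 95% bounds were 4.50-fold and 5.65-fold. Each of these 5 families was higher in the 5-Aza-CdR library than in PBS in both sets. In set 1, 90% of the LTR48B reads after 5-Aza-CdR came from 1 locus, and LTR12E had only 7 reads in PBS and 20 after 5-Aza-CdR.

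By group, 3 of the 8 LTR12 and HERV9 families tested rose after 5-Aza-CdR over all families, and 7 when adjusted over the list alone. The other 5 were LTR12_ (1.68, adjusted p = 0.056), LTR12B (2.26), LTR12D (1.11), HERV9-int (1.09) and LTR12F (0.58). Of the 3 families of the HERV-Fc list tested, 1 rose, and 2 did so when adjusted over the list alone. HERV-Fc1-int had an adjusted p of 0.0933 over all families. In the LTR7 and HERVH list 0 of 6 families passed, and 1 (LTR7Y, 1.83, adjusted p = 0.155 over all families) passed when adjusted over the list alone. In the MST list, 0 of 12 passed, and 1 (MSTB2, -1.64, adjusted p = 0.0553 over all families) was lower when adjusted over the list alone. No family passed, over all families or over the list alone, in LTR5 and HERVK (4 tested), LTR17 and HERV17 (2), LTR2 and HERVE (5), LTR10 and HERVI (7), MLT2 and HERVL (19), the MER families (89), or THE1 (9) and MLT1 (42), which are MaLR elements. The LTR2 and HERVE list includes HERVE_a-int, which the family sheet of set 1 gives with 0 reads although the locus sheets hold many. Internal regions numbered 91, of which 1 rose by either adjustment, and LTRs 261, of which 4 rose over all families; adjusted over the list alone, 5 LTRs rose and 1 fell.

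Within the sets, the median of the LTR12 and HERV9 families stood above nearly all matched random lists: its percentile after 5-Aza-CdR, rounded, was 100 in both sets. In set 1, scaled by tRNA, repeat reads in total were 3.03-fold those of PBS after 5-Aza-CdR (2.97 to 3.10; log2 1.60, or 0.84 from the locus sheets), and the median family stood 1.47 above PBS on the log2 scale, but at -0.13 per counted repeat read. The tRNA number was 6.09-fold lower than in PBS, and unscaled family reads were 0.499 of those in PBS. Of 107 families, 76 were at least 2-fold higher and 3 at least 2-fold lower by the tRNA scaling, and 14 and 14 per counted repeat read. In set 2, 7 of 143 families were at least 2-fold higher and 18 at least 2-fold lower per counted repeat read (median -0.35), but 12 and 7 by size factors (median 0.09). LTR12C was the highest of the families with the same direction in both sets (log2 5.26 in set 1 and 2.32 in set 2). HERVK3-int, MER66B, MLT1J1, MER52A and LTR5_Hs were also among the 10 highest, with joint log2 changes of 1.54, 1.37, 1.14, 1.08 and 0.94 that did not pass the test. The lowest were MLT1F1, MER101-int, MER41B and THE1-int, at -1.32, -1.12, -0.97 and -0.83, none past it; 777 of the 852 MLT1F1 reads in PBS of set 1 lay at 1 locus.

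LTR12C reads were counted at many copies, although how reads that map to several copies were assigned was not given. In set 1, 116 of 2740 LTR12C loci (4.23%) had reads in PBS and 759 (27.7%) after 5-Aza-CdR; in set 2 the numbers were 520 of 2656 (19.6%) and 1368 (51.5%). An LTR12C copy on chromosome 1 (175070212 to 175072001, hg19) had 7 reads in PBS and 40 after 5-Aza-CdR in set 1, and 0 and 142 in set 2. A copy on chromosome 13 (111473323 to 111474869) had 2 and 28 reads in set 1, and 1 and 50 in set 2. A HERVK3-int copy on chromosome 19 (58817484 to 58821622) had 14 and 36 reads, and 28 and 61. An MSTA copy on chromosome 8 (23046249 to 23046670) had 39 reads in PBS and 0 after 5-Aza-CdR in set 1, and 40 and 14 in set 2. In a fit of 409 loci, added after seeing the data, 80 rose and 28 fell, and 59 of the 104 LTR12C loci tested rose and 0 fell. Loci entered this fit by their reads summed over all libraries. LTR12C had 286 reads in PBS and 1807 after 5-Aza-CdR in set 1, and 851 and 5130 in set 2. The filter thus left its copies little room to be called lower. Leaving out any 5-Aza-CdR or Combination library left at most 1 locus, and dropping the term for the set left 0. Without PBS of set 1, 81 rose and 9 fell (56 of 102 LTR12C loci rose), and without PBS of set 2, 43 rose and 51 fell (29 of 99).

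The family calls after 5-Aza-CdR depended on the libraries used: without the 5-Aza-CdR library of set 1 only HERV-Fc2-int passed, without that of set 2 LTR12C and LTR12E were lost, and without the term for the set 0 families passed (20 at an unadjusted p under 0.05); leaving out the PBS library of set 1, the PBS library of set 2 or the Combination library of set 2 gave 39 (28 higher, 11 lower), 75 (38 and 37) and 10 families (7 and 3). Scaling by total reads gave 11 families (6 higher, 5 lower), and dropping the filter on low counts gave 11 (8 higher, 3 lower). Over all 13 alternatives the log2 changes kept their direction and ran from 2.75 to 3.68 for LTR12C, from 2.02 to 2.38 for LTR12 and from 2.12 to 2.79 for LTR12E.

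**Figure D2:**
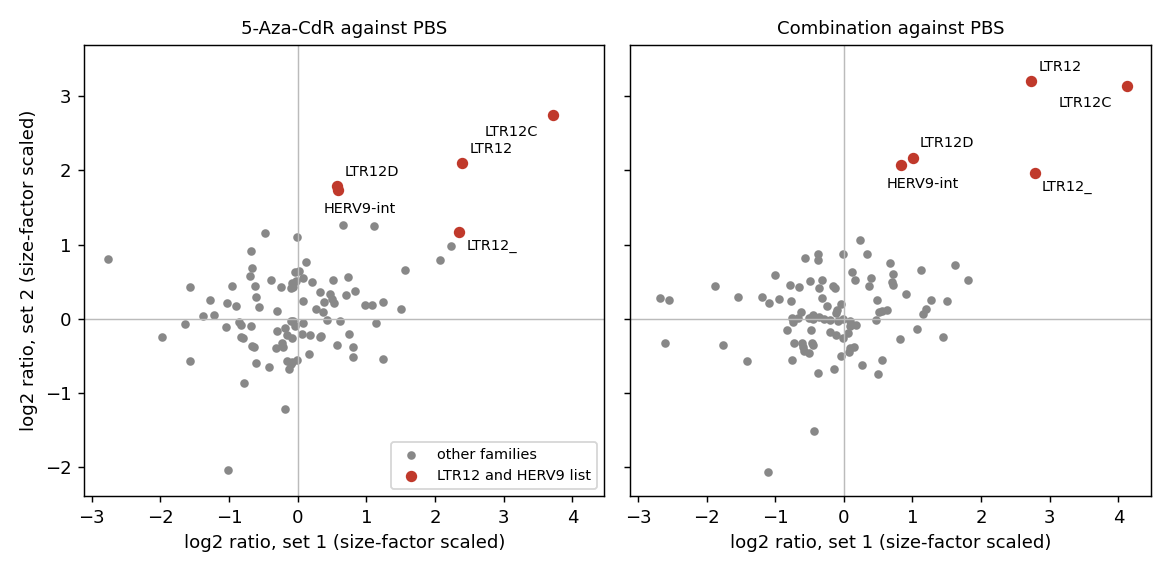
Log2 ratio to PBS of each of 99 families in set 1 (horizontal axis) and set 2 (vertical axis), scaled by median-of-ratios size factors, for 5-Aza-CdR (left) and the Combination (right); each point is a family and the red points are the LTR12 and HERV9 families. The red points lie in the upper right, with LTR12C at 3.71 and 2.75 after 5-Aza-CdR.

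The second comparison asks the same of the Combination against PBS. In the joint fit, 8 of 352 families rose and 1 fell. LTR12C rose by 3.58 on the log2 scale (SE 0.52, adjusted p = 0.00246), LTR12 by 2.97 (SE 0.35, adjusted p = 6.0e-04), LTR12E by 3.00 (SE 0.42, adjusted p = 0.00223) and LTR12_ by 2.31 (SE 0.38, adjusted p = 0.00561). HERV-Fc2-int (adjusted p = 2.4e-04) had 48 reads in set 1 and 106 in set 2 against 0 in both PBS libraries, at least 27.0-fold and at least 30.2-fold higher by the same floor and library sizes, with lower 95% bounds of 20.2-fold and 16.95-fold per counted repeat read. HERV-Fc1-int (adjusted p = 0.0136) had 9 and 36 reads against 0, at least 5.06-fold and at least 10.3-fold higher in the same way, with lower 95% bounds of 3.19-fold and 5.56-fold. LTR48B rose by 2.72 (SE 0.53, adjusted p = 0.0168) and LTR10F, an LTR of the HERV-I group, by 1.92 (SE 0.44, adjusted p = 0.0428). Each of these 8 families was higher in the Combination library than in PBS in both sets. In set 1 some rested on few reads: LTR10F had 2 in PBS and 11 in the Combination, and LTR12E had 7 and 46. Of the LTR48B reads in the Combination of set 1, 73.8% came from 1 locus.

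MSTB2, an LTR of the MaLR group, fell by 1.67 on the log2 scale (SE 0.36, adjusted p = 0.0332); its share of reads was lower in both sets, but scaled by tRNA its log2 ratio in set 1 was 1.99, above 0 like that of the median family. A single copy held most MSTB2 reads of PBS in each set: 170 of 191 reads at chromosome 5 (862748 to 862918) in set 2, and 52 of 86 at chromosome 2 (159941587 to 159941898) in set 1.

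By group, 4 of the 8 LTR12 and HERV9 families rose over all families, and 7 when adjusted over the list alone; LTR12D (1.53, adjusted p = 0.0562), HERV9-int (1.41), LTR12B (2.65) and LTR12F (0.49) did not pass over all families. Of the 3 families of the HERV-Fc list 2 rose, and of the 7 LTR10 and HERVI families 1 (LTR10F) rose, by either adjustment. Of 12 MST families 1 (MSTB2) fell by either adjustment. Among 91 internal regions 2 rose, and among 261 LTRs 6 rose and 1 fell, with the same numbers when adjusted over the list alone. No family passed by either adjustment in LTR7 and HERVH, LTR5 and HERVK, LTR17 and HERV17, LTR2 and HERVE, THE1, MLT1, MLT2 and HERVL or the MER families. HERVH-int, the internal region of HERV-H and an abundant family of set 2, had a joint log2 change of -0.24 (-1.13 to 0.65).

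Scaled by tRNA, total repeat reads in set 1 were 9.03-fold those of PBS (8.84 to 9.22; log2 3.17, or 2.48 from the locus sheets), with a median family at 2.98 on the log2 scale, but at -0.20 per counted repeat read. The tRNA number was 14.6-fold lower than in PBS, and unscaled family reads were 0.619 of those in PBS. At least 2-fold higher were 102 of 107 families and at least 2-fold lower 1; per counted repeat read these numbers were 12 and 15. In set 2, 8 of 143 families were at least 2-fold higher and 21 lower, with a median of -0.45, but by size factors 9 were higher and 5 lower, with a median of 0.08. The LTR12 and HERV9 families again stood at a rounded percentile of 100 in both sets. Other lists outside the limits were the MER families in set 1 (percentile 0.04 after 5-Aza-CdR and 0.61 after the Combination), MLT1 in set 2 (0.29 and 0.755) and internal regions in set 2 (98.6 after the Combination). With at least 20 counts the MER families after 5-Aza-CdR were at 13.4 and internal regions after the Combination at 83.3, both inside the limits. With single loci in place of families as list members, the MER families after the Combination were inside them at 3.15. In that ranking, which is of loci and not of families, internal regions turned to percentile 0. Of the families with the same direction in both sets, the highest after the LTR12 and HERV9 families were HERVK3-int, HERVIP10FH-int and HERV17-int, with joint log2 changes of 1.11, 0.84 and 0.69 that did not pass the test. The lowest, MER4-int, THE1C and MER21A, had joint changes of -0.23, 0.06 and 0.17, none past it, and in set 1 were higher only by tRNA (-1.08, -0.65 and -0.45 per counted repeat read).

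The provirus copy of HERV-Fc2-int on the X chromosome (97096856 to 97104052) carried 44 of the family's reads in the Combination library of set 1 and 93 in set 2, against 0 in both PBS libraries. An LTR12C copy on chromosome 4 (88316262 to 88317662) had 37 reads in the Combination library of each set and 0 in PBS. LTR12C copies with reads numbered 1128 in set 1 (41.2%) and 1658 in set 2 (62.4%). In the fit of loci, the filter again left LTR12C copies little room to be called lower. Of 409 loci fitted, 110 rose and 30 fell, with 86 of the 104 LTR12C loci rising and 0 falling; leaving out either 5-Aza-CdR or either Combination library left at most 2 loci, and dropping the term for the set left 0. Without PBS of set 1, 112 rose and 8 fell (88 of 102 LTR12C loci rose), and without PBS of set 2, 70 rose and 53 fell (51 of 99).

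**Figure D3:**
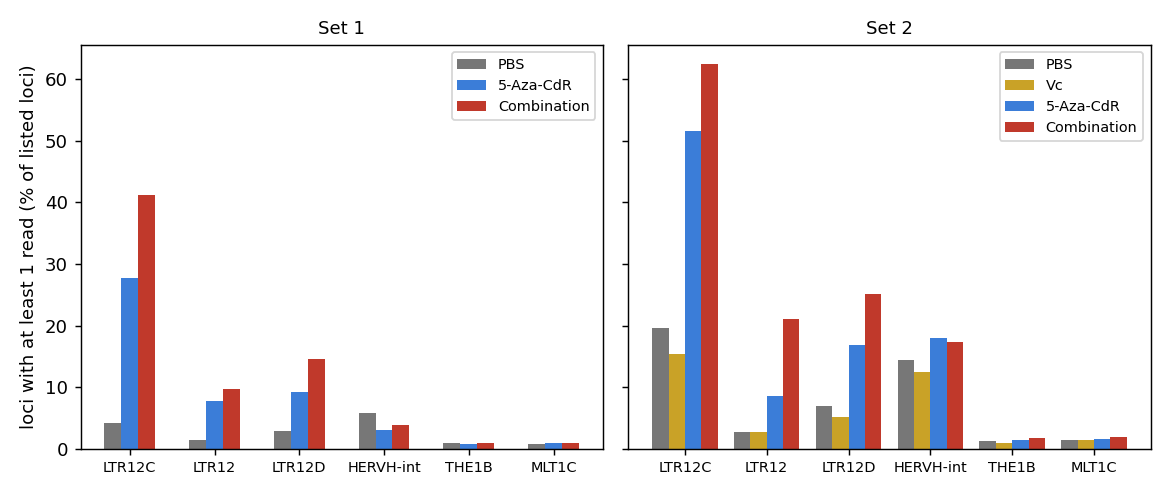
Share of annotated copies with at least 1 read (%, vertical axis) in 6 families (horizontal axis), by treatment, for set 1 (left) and set 2 (right); each bar is 1 library, and libraries differ in depth. LTR12C copies with reads went from 4.23% in PBS to 41.2% in the Combination of set 1 and from 19.6% to 62.4% in set 2, while THE1B and MLT1C stayed under 2%.

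Of the 9 families that passed after the Combination, HERV-Fc2-int and LTR12 passed in all 13 alternative fits. LTR12C, LTR12E and LTR12_ were lost only without the term for the set, which left 2 families in all. HERV-Fc1-int was also lost without the Combination library of set 2, LTR48B without that of set 1, and LTR10F and MSTB2 without either one or without the 5-Aza-CdR library of set 1; LTR10F was also lost in DESeq2 and with total reads. Leaving out the PBS library of set 1 or of set 2 gave 31 (22 higher, 9 lower) and 66 families (34 and 32), total reads 17 (9 higher, 8 lower) and no filter 15 (11 higher, 4 lower).

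The third comparison asks what the Combination added to 5-Aza-CdR. HERV-Fc2-int had 48 reads in the Combination and 10 in 5-Aza-CdR of set 1, and 106 and 27 in set 2. With the library sizes of the joint fit these are ratios of 4.04 (2.02 to 8.97) and 3.06 (1.99 to 4.86), and by tRNA in set 1 the ratio was 11.5, but the family did not pass in the joint fit (adjusted p = 0.618). HERV-Fc1-int had 9 and 3 reads in set 1, and 36 and 10 in set 2, with ratios by the library sizes of the joint fit of 2.53 (0.631 to 14.5) and 2.81 (1.36 to 6.34). LTR12 stood 0.76 higher on the log2 scale (0.06 to 1.45) and LTR12C 0.42 higher (-0.61 to 1.46), neither past the threshold. Of 352 families fitted jointly, 0 passed in edgeR (9 at an unadjusted p under 0.05) and 0 in DESeq2 (2 unadjusted). Leaving out the PBS library of set 1 gave 11 families, and leaving out that of set 2 gave 2.

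No list had a family past the threshold over all families in this comparison, and 1 of 3 families of the HERV-Fc list passed when adjusted over the list alone. Within the sets the median of the LTR12 and HERV9 families was at percentile 99.9 in set 1 and 99.7 in set 2. By tRNA scaling in set 1, repeat reads in total were 2.97-fold higher in the Combination (2.90 to 3.05), and 96 of 107 families were at least 2-fold higher and 0 lower (median 1.47), but per counted repeat read 0 were at least 2-fold higher and 2 lower (median -0.10). In set 2, 2 of 143 families were at least 2-fold higher, LTR12 and HERV-Fc2-int, and 4 lower, LTR46, MER51A, MER65C and LTR2. Among families higher in both sets, MER21B, HERVIP10FH-int and MLT2B1 followed LTR12 and LTR12_, with joint log2 changes of 0.57, 0.53 and 0.46 that did not pass; those with the smallest ratios were MER41-int, THE1A and THE1D-int, with joint changes of -0.05, -0.11 and -0.05, and in set 1 they were higher only by tRNA (-0.62, -0.45 and -0.56 per counted repeat read). Of 409 loci, 0 passed in edgeR (4 unadjusted); leaving out the PBS library of either set gave 3.

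The fourth comparison, of Vc alone with PBS, rests on 1 library of set 2, so the spread used in its test comes from the other treatments alone. LTR12C held 4.25% of family reads after Vc and 4.38% in PBS, and its joint log2 change was 0.21 (-1.10 to 1.52). HERV-Fc2-int had 1 read after Vc and 0 in PBS. In the joint fit 0 of 352 families passed in edgeR (5 unadjusted) and 0 in DESeq2 (1 unadjusted), and no family of any list passed over the list alone; leaving out the PBS library of set 2 gave 38 families. Without that library Vc is compared with PBS of set 1, through the term for the set, and not within a set. The LTR12 and HERV9 families were at percentile 26.5, and internal regions at 97.7, or at 50 with single loci as list members, inside the limits. Of 143 families, 2 were at least 2-fold lower, MER74B (-1.15) and LTR10F (-1.04), and 1 at least 2-fold higher, HERV-Fc2-int, from its single read. LOR1-int went from 44 reads in PBS to 84, and LTR46 had a log2 ratio of 0.94; the median of all families was 0.06. By locus, a HUERS-P1-int copy on chromosome 5 (137765896 to 137765964) had 5 reads in PBS and 38 after Vc, and the HERVK3-int copy on chromosome 19 named above had 28 and 6.

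The last comparison sets the Combination beside the sum of the log2 ratios of 5-Aza-CdR and Vc alone in set 2. Over 143 families the difference had a median of -0.09 (SD over families 0.55), with 61 families above the sum and 82 below it. By size factors the median was 0.04. At least 2-fold above the sum were LTR10F (1.61), MER74B (1.27), LTR12_ (1.23) and LTR12 (1.05). HERV9-int (0.65), LTR12C (0.33) and LTR12E (0.17) were less far above it and LTR12D lay at -0.14. These differences carry no interval and some rest on few reads: MER74B had 38, 16, 30 and 45 in PBS, Vc, 5-Aza-CdR and the Combination. LTR10F and MER74B were also the families at least 2-fold lower after Vc, which enters the difference with reversed sign. Of 11 families at least 2-fold below the sum, the lowest were LTR46 (-2.29), MER51A (-1.74) and MLT1J1 (-1.52). In the joint fit 0 of 352 families differed from the sum in edgeR (4 unadjusted) and 0 in DESeq2 (1 unadjusted), in no list was there a family past the threshold over the list alone, and all 8 LTR12 and HERV9 estimates lay above 0. This contrast too rests on the single Vc library, with its spread taken from the other treatments, so that 0 families does not show that the effects add. Without PBS of set 2 this contrast also sets Vc against PBS of set 1, through the term for the set. The 8 LTR12 and HERV9 estimates share the same libraries and are not 8 separate results, and in set 2 LTR12D lay below the sum. Leaving out the PBS library of set 1 gave 3 families and leaving out that of set 2 gave 31.

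Across 99 families with at least 100 reads in both sets, log2 ratios scaled by size factors correlated between the sets with a Pearson r of 0.43 for 5-Aza-CdR, 0.51 for the Combination and 0.29 for the Combination against 5-Aza-CdR. Without the LTR12 and HERV9 families these values were 0.20, 0.18 and 0.20 over 94 families. Families with the same sign in both sets numbered 61, 54 and 60 of 99. By the scaling used for each set, which in set 1 raises nearly all families by the tRNA number, 31 families had the same direction after 5-Aza-CdR (27 higher), 18 after the Combination (all higher) and 42 in the Combination against 5-Aza-CdR (all higher), so these numbers mostly restate which families were higher in set 2.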

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

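Of the tests below, 5, and the values per counted repeat read, were chosen only after the result was seen, and 1, that of MSTB2 in set 1, was written before its value was computed.

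In the locus sheets of set 1, 1 HERVE_a-int locus on chromosome 6 (4428317 to 4428782) held 80.2% of all locus reads in PBS, 58.2% in 5-Aza-CdR and 61.7% in the Combination, while the family sheet lists HERVE_a-int with 0 reads. Its tRNA-scaled ratio of the Combination to PBS was 4.28 (4.22 to 4.33) and its unscaled ratio 0.293, so its direction depended on the scaling. It was singled out because its reads in set 1 stand outside the family counts on which the comparisons rest. The joint fit tested HERVE_a-int as a family of the LTR2 and HERVE list, with 0 reads in set 1. In set 2 the same locus had 8, 7, 7 and 5 reads in PBS, Vc, 5-Aza-CdR and the Combination. A MER11B locus on chromosome 3 (15779666 to 15780942), of a family absent from the family sheet of set 1 as used here, had 3239, 4788 and 5144 reads in PBS, 5-Aza-CdR and the Combination, a tRNA-scaled ratio of the Combination to PBS of 23.2 (22.2 to 24.2) and an unscaled ratio of 1.59. In set 2 it had 87, 54, 90 and 87 reads. Neither difference was tested.

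The larger share of LTR12 reads was weighed against 3 technical explanations. Were it due to a few loci holding most of the counted reads, LTR12C would lose its increase without its top loci. The 10 loci with most reads of each library were left out. The smallest of its 4 log2 ratios to PBS was then 2.88 by size factors (2.77 to 3.01, and 2.75 with all loci). Per counted repeat read it was 2.45 (2.33 to 2.57, and 2.32 with all loci). Leaving out the loci with most PBS reads tends to raise the ratio, so a value above that with all loci is no added support. The loci with most treated reads were left out too. In set 2, 4369 of 5130 LTR12C reads remained after 5-Aza-CdR, against 661 of 851 in PBS. Were the larger share due to scaling, some scaling would remove it. The smallest ratio over all scalings, unscaled reads included, was 2.32 (2.21 to 2.42). For LTR12C the values argue against both explanations, as reads were counted. Were the reads of LTR12, LTR12_, LTR12D and LTR12E merely shared from LTR12C copies, their gain would be the same percent of the LTR12C gain under both treatments. The Combination exceeded 5-Aza-CdR by 2.09 percentage points in set 2 (0.78 to 3.47) but by 1.38 in set 1 (-0.94 to 3.69), so shared reads stay open for the smaller LTR12 families, and reads of few LTR12C copies spread over similar ones, and PCR duplicates, were not tested.

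Most families stood higher than PBS in set 1 only by the tRNA numbers. Without them the median log2 ratio of unscaled reads was -1.13 after 5-Aza-CdR and -0.89 after the Combination. A difference in tRNA recovery between the libraries could account for the increase, as could more repeat RNA relative to tRNA in the treated cells. The sheets give no sequencing depth and no other reference amount, and the values here cannot tell these accounts apart, so the question stays open.

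The lower share of MSTB2 could rest on a single copy. Without the locus on chromosome 5 (862748 to 862918), the log2 ratio of the Combination to PBS in set 2 went from -2.07 to -0.13 by size factors (-1.06 to 0.80), and from -2.60 to -0.67 per counted repeat read (-1.60 to 0.27). Without the locus on chromosome 2 (159941587 to 159941898), that in set 1 went from -1.11 to 0.0190 by size factors (-0.87 to 0.84), and from -1.19 to -0.0591 per counted repeat read (-0.95 to 0.76). Each set met the prediction for a single locus, a different locus in each set. However, leaving out the locus that held most PBS reads tends to raise the ratio whatever the cause, so the test shows only where the decrease lay. With 21 PBS reads left in set 2 and 34 in set 1, the intervals are wide and leave room for a smaller decrease of the other MSTB2 copies.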

How the results depend on the processing

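The fits of loci, of Vc alone and of the sum of the single agents, and robust dispersion, were chosen only after the results were seen. Of the counts and totals under other settings, 90 moved and 95 stayed the same; of the values for single families and lists, 1127 stayed the same, 75 moved, 73 became stronger, 32 became weaker and 5 reversed. With at most 2 libraries per treatment, counts past the threshold moved with the libraries left out, and counts at 2-fold with the filter. No family that passed turned direction in any of 13 alternatives, but none of these used the tRNA scaling. By that scaling MSTB2, lower after the Combination in the joint fit, had a log2 ratio to PBS of 1.99 in set 1. The tRNA scaling could not be run for set 2, and totals scaled by total reads are 0 by construction. Except there, and in the fits without a PBS library of 1 set, where the difference between the PBS libraries leaves the residual spread by construction, the cause of a changed result was not tested.

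Total repeats in set 1 (log2) for 5-Aza-CdR, the Combination and the Combination against 5-Aza-CdR were 0, 0 and 0 with total reads; 0.0525, 0.0780 and 0.0256 with size factors; 0.84, 2.48 and 1.64 from the locus sheets; and 1.42, 2.91 and 1.49 without the 5 most abundant families. In set 2 they were 0.44, 0.54 and 0.10 with size factors (Vc -0.0333), -0.30, -0.36 and -0.0629 without the 5 most abundant families (Vc 0.0506), and -2.2e-04 from the locus sheets for 5-Aza-CdR, the Combination and Vc. The median difference from the sum of the single agents was 0.0409 with size factors.

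Families at least 2-fold different in set 1, in the same order, numbered 28, 27 and 2 with total reads, 27, 28 and 2 with size factors, 205, 276 and 237 with at least 20 counts, 373, 469 and 383 with no filter, and 10, 17 and 17 with at least 500 counts. In set 2, with Vc last, they numbered 106, 104, 44 and 40 with at least 20 counts, 173, 171, 102 and 103 with no filter, 7, 6, 0 and 0 with at least 500 counts, and 61, 60, 18 and 16 at 1.5-fold. For the Combination in set 2 the number was 14 with size factors and 12 without the 5 most abundant families, and for Vc 0 with a pseudocount of 5.

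In the joint fit, families past the threshold for 5-Aza-CdR and for the Combination numbered 11 and 17 with total reads, 11 and 15 with no filter, and 0 and 2 with no replicate block, that is, without the term for the set; robust dispersion left 5 and 9. Leaving out each library in turn gave 1 to 75 families for 5-Aza-CdR, 6 to 66 for the Combination, 0 to 11 for the Combination against 5-Aza-CdR, 0 to 38 for Vc and 0 to 31 for the difference from the sum. For loci it gave 0 to 94, 0 to 123 and 0 to 3; with no replicate block 0 and 0 loci passed, and with at least 60 counts 26 and 28. Of 67 list percentiles, 12 lay outside the limits (8 high and 4 low), and 28 did with single loci as list members (7 high and 21 low). Lists of loci differ in size from lists of families, so the 2 counts are of unlike measures. With loci, internal regions for the Combination in set 2 turned from high to percentile 0. Leaving out each library in turn, the log2 change after 5-Aza-CdR ran from -0.46 to 0.55 for MSTA-int, from -0.60 to 0.61 for THE1B and from -0.78 to 0.60 for THE1C, and that of THE1C after the Combination from -0.58 to 0.80. Without PBS of set 1 the positive values after 5-Aza-CdR passed the threshold (adjusted p = 0.0312, 0.00857 and 0.0123), as did the negative THE1C value without PBS of set 2 (adjusted p = 0.0189).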

Other observations

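The shares, loci and correlations below were selected after the results were seen, and no test was made of them.

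HERVH-int, the internal region of HERV-H, a group of proviruses known for transcription in pluripotent cells, was among the most abundant families without passing the test. In set 1 it held 3.60% of family reads in PBS (832 reads) and 2.27% in 5-Aza-CdR (262 reads), and had 358 reads in the Combination; in set 2 it held 11.9% in PBS, 9.39% in Vc, 10.8% in 5-Aza-CdR and 8.49% in the Combination. A HERVH-int copy on chromosome 1 (68852826 to 68855367) had 161, 32 and 75 reads in set 1, and 169, 109, 97 and 176 in set 2. The adjoining HERVH-int fragment (68855487 to 68855986) had 49, 1 and 2 reads, and 42, 43, 31 and 64. Listed HERVH-int loci with reads made up 5.84% in PBS and 3.91% in the Combination of set 1, and 14.5% and 17.3% in set 2.

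Reads also lay on LTR12 copies outside LTR12C. LTR12 loci with reads made up 1.42%, 7.75% and 9.69% in PBS, 5-Aza-CdR and the Combination of set 1, and 2.78%, 2.78%, 8.60% and 21.0% in PBS, Vc, 5-Aza-CdR and the Combination of set 2. An LTR12D copy on chromosome 19 (8451280 to 8451985) had 23, 4 and 12 reads in set 1, and 11, 28, 86 and 104 in set 2. The 10 LTR12C loci with most reads held 40.2% of LTR12C reads in PBS and 15.9% in the Combination of set 1, and 19.3% and 10.5% in set 2. An LTR12C copy on chromosome 10 (74060187 to 74061778) had reads in all libraries of set 2: 94, 133, 101 and 114, not scaled to depth.

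The PBS library of set 1 was less like the treated libraries of its set than that of set 2. Over 193 families its Spearman correlations were 0.72 with 5-Aza-CdR and 0.71 with the Combination of set 1, against 0.86 and 0.85 for PBS of set 2 with those treatments of set 2. The treated libraries of set 1 correlated with each other at 0.92, PBS and Vc of set 2 at 0.94, and 5-Aza-CdR and the Combination of set 2 at 0.93. Between sets the correlations ran from 0.60 to 0.69 for this PBS library and from 0.67 to 0.78 for 5-Aza-CdR and the Combination of set 1. In this PBS library 12.4% of family reads lay in 10 loci, against 8.98% in 5-Aza-CdR and 5.81% in the Combination of set 1, and 4.50% in PBS of set 2. An MLT1F1 locus on chromosome 5 (36221359 to 36221589) had 777 reads there, 45 in 5-Aza-CdR and 23 in the Combination, and 2, 0, 1 and 0 in set 2. A pair of adjoining LTR25 loci on chromosome 9 had 270 and 265 reads in that library and 0 in all of set 2. A THE1D locus on chromosome 2 (186839091 to 186839260) had 234, 2 and 5 reads in set 1.

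In set 2, an MLT1A1 locus on chromosome 5 (860625 to 860972), near the MSTB2 locus with most reads, had 121, 114, 10 and 5 reads in PBS, Vc, 5-Aza-CdR and the Combination, and 0 in set 1. A MER21C locus on chromosome 1 (91852713 to 91852785) had 704, 397 and 320 reads in set 1, and 13, 10, 15 and 15 in set 2.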
